A study of Mus musculus with 12 samples.

How the data were processed

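RNA was extracted from B220+ splenocytes of 12 mice, 3 per genotype, and sequenced on libraries prepared by standard Illumina protocols, per the labels. Per the submitters' processing notes, base calls were converted with bcl2fastq 1.8.4, reads were handled with TopHat2 2.1.0 and HTSeq 0.6.1, and the genome build was mm10. The deposited values are whole-number read counts per gene symbol, 1 table per mouse, which the authors made before any normalization. The gene annotation, the strand setting of the counting and the read length are not given in the sources used here. Reads from overlapping or antisense genes, and genes with near-identical copies such as ribosomal proteins, are therefore uncertain. The files also hold 5 summary rows that name no gene, and these stayed out of library sizes and tests. As a share of all reads in the tables, reads outside annotated genes made up 18.8% ± 1.84 (SD, n = 3) in WT, 20.0% ± 0.41 in Max KO, 13.1% ± 0.573 in EuMyc and 16.9% ± 1.78 in EuMyc Max KO. Reads that mapped to more than 1 place made up 22.1% ± 1.60, 22.1% ± 0.88, 21.8% ± 1.05 and 25.8% ± 2.81 in the same order, and ambiguous reads stayed between 0.798% and 1.18% as group means.

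Groups were taken from the genotype labels and replicate numbers from the titles. Each library holds cells of 1 mouse, per the labels. No pair of files was identical, and every pair within a group differed by more than sampling noise, with a chi-square per degree of freedom of 7.86 to 70.1. The deposited counts were analysed with R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Genes were filtered by edgeR's filterByExpr on the 4 groups, which left 12878 of 24421 genes. Libraries were scaled by TMM, and 1 quasi-likelihood model (glmQLFit with robust = TRUE, glmQLFTest) was fitted to all 12 libraries with 8 residual degrees of freedom, so that the groups share an estimate of the spread. The common biological coefficient of variation was 13.7%. The 6 contrasts tested were Max KO against WT, EuMyc against WT, EuMyc Max KO against EuMyc, EuMyc Max KO against Max KO, EuMyc Max KO against WT, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. With 3 mice against 3, an exact two-sided permutation test of a single gene cannot go below p = 0.1, so calls rest on the model's pooled spread. CPM values use the TMM-scaled library sizes. All values are relative to the RNA sequenced per library: a change in the amount of RNA per cell cannot be read from them.

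Gene lists, contrasts, alternatives and the rule for named genes were fixed before the data were examined. Of 44 lists, 42 had at least 5 tested genes and entered limma's camera test with a preset correlation between genes of 0.01, repeated with an estimated correlation. Within a contrast, camera's p was adjusted over the lists by Benjamini-Hochberg. Lists could share genes, so their results are not independent. Of 68 tested MYC target genes 42 were also in another list, and of 86 ribosome biogenesis genes 25 were. Beside the calls over all genes, each list was also adjusted alone. The named genes are Max and Myc, and for the 3 main contrasts (the first 3 above) the 10 genes with the highest and the 10 with the lowest log2 fold change among those called, with a mean CPM of at least 5 over the 6 libraries and with all 3 libraries of a group above all 3 of the other. For the interaction the rule takes 5 and 5, without the last condition, and for the remaining contrasts 3 and 3. From each list up to 4 called members with the smallest p were added (2 with the highest CPM if none was called), and each called gene of the MYC and MAX network. Immunoglobulin and T cell receptor segments, unnamed gene models, small RNA genes and haemoglobin genes stayed out of the top lists. The text names a part of these genes, chiefly those whose calls did not depend on a single library. Coordinates are those of GENCODE vM21 on mm10, which held 23376 of the 24421 symbols (95.7%).

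The pipeline was tested on simulated counts drawn from the real means and library sizes with a fixed seed, with 67, 67 and 66 genes changed by 1.5-, 2- and 4-fold. For Max KO against WT it recovered 59.7%, 74.6% and 90.9% of them, with 9 false calls among 159 over 12701 genes. The same shares were 52.2%, 76.1% and 90.9% for EuMyc against WT (12 of 158 calls false, 12732 genes), 58.2%, 68.7% and 93.9% for EuMyc Max KO against EuMyc (7 of 154, 12711 genes), 67.2%, 76.1% and 92.4% for EuMyc Max KO against Max KO (6 of 163, 12713 genes), 61.2%, 79.1% and 89.4% for EuMyc Max KO against WT (8 of 161, 12700 genes) and 38.8%, 59.7% and 80.3% for the interaction (7 of 126, 12706 genes). In a simulated comparison with no changed genes, 1 of 42 lists was called. The simulated genes varied independently of each other, so this does not measure false list calls where the genes of a list are correlated.

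Alternatives changed 1 choice at a time: RLE size factors, upper-quartile factors or library totals for TMM, no filter on low counts or a CPM of at least 1 in 3 libraries, DESeq2 1.42.0 and limma-voom, a fit of the compared libraries only, the replicate number as a block, a test against 1.5-fold, haemoglobin genes left out, each library left out in turn, and for the lists the estimated correlation and the fry test. List medians under RLE and upper-quartile factors, a sex term and a fit without the 2 EuMyc Max KO libraries rich in erythroid transcripts were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The 2 lists with fewer than 5 tested genes were left out, and exon usage and transgene-specific reads were not analysed here. The results of 4 single genes are not reported here.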

Results

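RNA from B220+ splenocytes was sequenced from 12 mice aged 4 to 5 weeks. B220 is a form of CD45 carried by B cells from the pro-B stage onward and also by plasmacytoid dendritic cells. The mice fell into 4 groups of 3: mice with intact Max (WT), conditional Max knockout mice (Max KO), EuMyc mice with intact Max, and EuMyc Max KO mice. EuMyc is a transgene in which the immunoglobulin heavy chain enhancer drives Myc in B lineage cells. It leads to B cell lymphoma, and the series title describes the cells sampled here as premalignant. MAX is the obligate dimerisation partner through which MYC binds DNA, and it also pairs with MXD1, MXI1, MXD3, MXD4, MNT and MGA. The design asks what loss of Max changes in normal B cells, what the Myc transgene changes, and how far the transgene's changes need Max. Between 14973332 and 21671601 reads per library were assigned to genes: 16629314 to 17647732 in WT, 14973332 to 17125122 in Max KO, 20221681 to 21671601 in EuMyc and 17890935 to 18668193 in EuMyc Max KO. Values per gene are in CPM, the count of a gene scaled to the same total in every library, given as mean ± SD over n = 3 mice, and log2 fold changes carry their standard error (SE).

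Max (mm10 chromosome 12, 76937269 to 76962201, minus strand, protein coding) was read in every library. Its CPM was 139, 110 and 108 in the WT libraries, 102, 102 and 99.8 in Max KO, 126, 127 and 130 in EuMyc and 108, 104 and 102 in EuMyc Max KO. All 6 libraries labelled as knockouts lay below all 6 with intact Max. The log2 fold change was -0.23 (SE 0.0784) for Max KO against WT, with an adjusted p of 0.0623 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For EuMyc Max KO against EuMyc it was -0.29 (SE 0.0781), with an adjusted p of 0.00462 by the same edgeR test. Counts per gene do not separate exons, so transcripts that lack a deleted exon are still counted here and the level does not measure how complete the deletion was. Myc (chromosome 15, 61985391 to 61990374, plus strand) was at 106 ± 9.37 CPM in WT, 126 ± 8.37 in Max KO, 1010.4 ± 37.1 in EuMyc and 522 ± 39.5 in EuMyc Max KO. Transgene and endogenous transcripts are not told apart in these counts. Max KO exceeded WT by 0.26 log2 units, with an adjusted p of 0.0483 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That call was lost without WT replicate 2, WT replicate 3 or any of the 3 Max KO replicates, with an adjusted p of up to 0.185. The EuMyc libraries carried 3.26 log2 units more Myc than WT (SE 0.0872; adjusted p = 7.52e-11, edgeR quasi-likelihood test, Benjamini-Hochberg). EuMyc Max KO libraries carried less than EuMyc libraries, by -0.95 log2 units (SE 0.0802; adjusted p = 2.5e-07, same test), yet 2.31 more than WT.

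**Figure D1:**
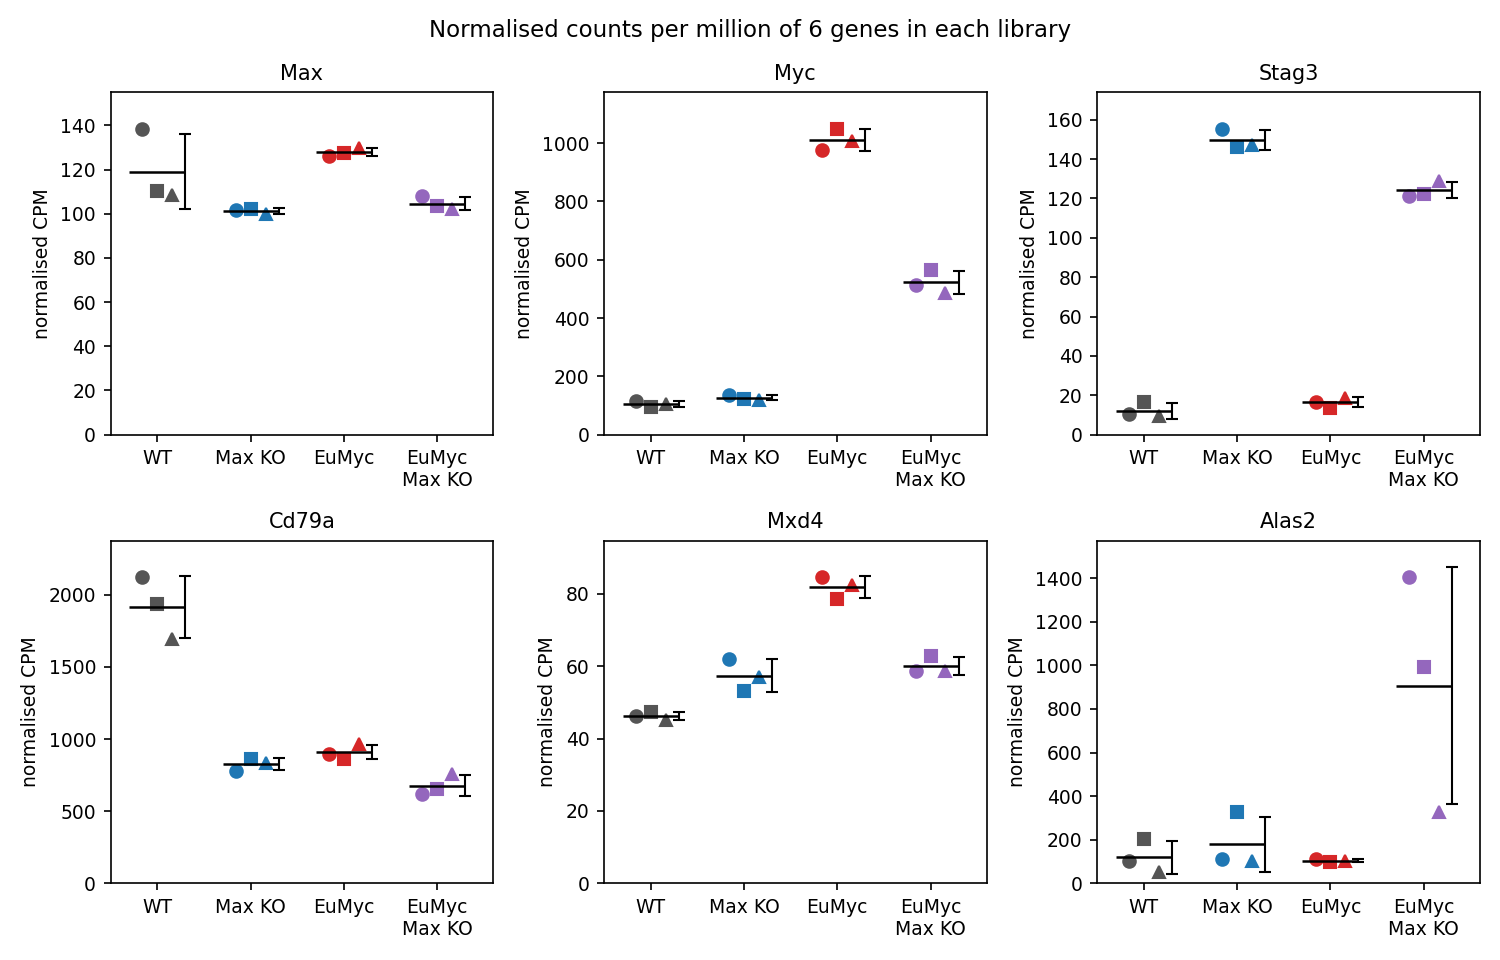
CPM of Max, Myc, Stag3, Cd79a, Mxd4 and Alas2 in each of the 12 libraries, 1 panel per gene; points are libraries (circle, square and triangle for replicates 1, 2 and 3), horizontal lines are group means and bars are SDs over n = 3. Stag3 stood at 150 ± 5.10 CPM in Max KO and 124 ± 4.22 in EuMyc Max KO against 12.1 ± 3.97 in WT, and Alas2 reached 1405 CPM in EuMyc Max KO replicate 1.

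Max KO cells were compared with WT cells for what Max loss changes in normal B220+ cells. Of the gene lists, those of the germinal centre reaction (9 of 15 genes), G2 and mitosis (24 of 52), cytosolic ribosomal proteins (58 of 79) and oxidative phosphorylation (24 of 61) held genes that fell and none that rose, and 4 of 11 germline genes rose. With an estimated correlation between genes the germinal centre call held, and the others were lost at adjusted p = 0.541, or 0.109 for the germline genes, with an estimated correlation. The clearest single gain was Stag3, a meiotic cohesin subunit (chromosome 5, 138280240 to 138312393), which went from 12.1 ± 3.97 to 150 ± 5.10 CPM (log2 fold change 3.62, SE 0.184). Among the 10 largest decreases, S1pr2, a receptor that keeps B cells within germinal centres, fell from 13.6 to 1.69 CPM (log2 fold change -3.00, SE 0.202), and Mybl1, a MYB family factor of germinal centre B cells, fell from 16.7 to 2.25 CPM (-2.87). Gcsam, a germinal centre signalling protein, fell by 2.80 on the log2 scale and Eaf2 by 2.15.

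Of 15 germinal centre genes tested, 9 fell and none rose over all genes, with 9 and 0 adjusted over the list alone, and the median log2 fold change was -0.74. Camera, which compares a list with all other genes, gave an adjusted p of 6.16e-21, and this was the only list of the 22 called in Max KO against WT whose call held with an estimated correlation (adjusted p = 0.014 with an estimated correlation). Among 52 G2 and mitosis genes 24 fell and 0 rose (37 and 0 adjusted over the list alone), with a median of -0.92 and examples in Bub1b, a spindle checkpoint kinase (-1.40, SE 0.259), and Cks1b, a subunit of cyclin-dependent kinases (-0.92, SE 0.168). Among 52 S phase genes 21 fell and 2 rose (35 and 2 adjusted over the list alone), with a median of -0.40. Hells, a chromatin remodeller of replicating cells, fell by 0.60 and Cdca7, its partner, by 0.79. Camera's adjusted p was 2.51e-18 for G2 and mitosis and 5.86e-10 for S phase, and each call was lost with adjusted p = 0.541 with an estimated correlation.

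Several lists of protein synthesis and energy metabolism had medians slightly below 0, and others were mixed. Of 79 cytosolic ribosomal protein genes 58 fell and 0 rose (74 and 0 adjusted over the list alone), with a median of -0.35. Rpl32 fell from 855 to 537 CPM (log2 fold change -0.67, SE 0.102), and Rps18 fell by 0.47. Ribosomal proteins have many processed pseudogenes, so reads that map to both could have been dropped. Of 61 oxidative phosphorylation genes 24 fell and 0 rose (38 and 0 adjusted over the list alone; median -0.21), and of 40 proteasome and chaperone genes 16 fell and 0 rose (28 lower and 1 higher adjusted over the list alone; median -0.20). Translation factors and tRNA synthetases gave 20 lower and 0 higher of 42 (26 and 0 adjusted over the list alone; median -0.20), with Eef1b2, a translation elongation factor, at -0.44 (SE 0.082). Camera's adjusted p was 2.27e-28 for the ribosomal proteins, 6.01e-10 for oxidative phosphorylation, 8.57e-08 for the proteasome list and 4.93e-09 for the translation factors, each lost at adjusted p = 0.541 with an estimated correlation. MYC target genes were mixed: 25 of 68 fell, among them Pa2g4, a nucleolar growth regulator (-0.52, SE 0.0606), and 9 rose, with 28 and 13 adjusted over the list alone and a median of -0.13. Camera gave 0.0142 for that list (adjusted p = 0.66 with an estimated correlation), and without WT replicate 1 its adjusted p was 0.139. Ribosome biogenesis genes gave 19 lower and 10 higher of 86 (26 and 12 adjusted over the list alone; median -0.08) and glycolysis genes 3 lower and 3 higher of 21 (6 and 4 adjusted over the list alone; median -0.08), and camera called neither (adjusted p = 0.0679 and 0.431), although ribosome biogenesis was called lower without WT replicate 2 or Max KO replicate 3 (adjusted p down to 0.00525). Phgdh, the enzyme that opens serine synthesis, fell from 72.8 ± 1.797 to 51.3 ± 0.107 CPM.

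Other gene lists had medians above 0 without Max. Of 11 tested germline genes known as targets of silencing by MAX, MGA and E2F6, 4 rose and 0 fell (5 higher and 2 lower adjusted over the list alone; median 0.74; camera adjusted p = 6.96e-05, adjusted p = 0.109 with an estimated correlation). Beside Stag3 they included Zcwpw1, a histone reader of meiotic cells (30.0 to 50.2 CPM, log2 fold change 0.74), and Tdrkh, of the piRNA pathway (0.99). The germline list held 30 genes, of which 11 passed the filter on counts, 7 of them at 1 CPM or more in WT. The filter took all 4 groups together, so a gene could enter through the libraries without Max alone. The share of tested genes that rose is therefore not the share of the whole list. Mga and Mnt, partners of MAX, rose by 0.80 and 0.73 on the log2 scale, and Mnt went from 74.9 ± 6.92 to 124 ± 3.68 CPM. Of 21 marginal zone B cell genes 8 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.37; camera adjusted p = 0.00049, adjusted p = 0.516 with an estimated correlation). Cd1d1, which presents lipids, rose by 0.54 and Dtx1, a NOTCH regulator, by 0.59. NF-kB target genes gave 9 higher and 0 lower of 22 (10 and 0 adjusted over the list alone; median 0.23; camera adjusted p = 0.00014, adjusted p = 0.541 with an estimated correlation), among them Ebi3 (0.61) and Lta (0.57). The cyclin Ccnd2 rose from 110 to 201 CPM (log2 fold change 0.86), Il9r, the interleukin 9 receptor, from 85.6 to 332 CPM (1.95), and Nr1d1, a circadian repressor, from 1.92 to 8.33 CPM (2.12). The pro-apoptotic Bmf fell from 85.1 to 40.3 CPM (-1.08, SE 0.109). Cd79a, the signalling chain of the B cell receptor (chromosome 7, 24897381 to 24902197), fell from 1917 ± 216 to 825 ± 42.7 CPM (-1.22, SE 0.0971), while the median of the other 24 B cell identity genes was -0.07.

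Lists of markers of cell types outside the B lineage had medians above 0, and most of their genes did not pass the test. Of monocyte and macrophage markers 7 of 22 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.76 and Apoe going from 276 to 588 CPM. Camera gave 1.73e-09 for that list (adjusted p = 0.541 with an estimated correlation). Neutrophil markers gave 2 higher and 0 lower of 12 (median 2.14; camera adjusted p = 0.00163), NK cell markers 0 and 0 of 13 (median 0.74; camera adjusted p = 0.00209) and dendritic cell markers 3 and 0 of 16 (median 0.55; camera adjusted p = 0.00163), each with the same numbers adjusted over the list alone and each lost at adjusted p = 0.541 with an estimated correlation. T cell markers gave 2 higher and 0 lower of 23, also adjusted over the list alone (median 0.26; camera adjusted p = 0.0351, adjusted p = 0.612 with an estimated correlation). The neutrophil call was lost without Max KO replicate 2 (adjusted p = 0.0892), and the T cell call without WT replicate 1 or Max KO replicate 1 or 2 (adjusted p up to 0.205). Of 12878 genes tested, 1933 differed between Max KO and WT (936 higher, 997 lower) at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 412 of them differed by over 2-fold. That count was 808 without WT replicate 1, 1206 without WT replicate 3, 889 without Max KO replicate 1 and 1060 without Max KO replicate 2. Scaled by library totals alone, the calls split into 1130 higher and 719 lower.

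The Myc transgene in cells with Max was compared next. EuMyc cells had more of the transcripts of the cell cycle, ribosome biogenesis, oxidative phosphorylation, nucleotide synthesis and pro-B and pre-B cells, and less of those of mature B cells. Glycolysis genes were mixed, with 12 higher and 5 lower of 21 (camera adjusted p = 0.00162). Cholesterol and fatty acid genes gave 13 higher and 3 lower of 27 and were not called (camera adjusted p = 0.0949). With an estimated correlation camera called 0 of 42 lists here. Rag1, the V(D)J recombinase (chromosome 2, 101638282 to 101649501), rose from 2.84 to 337 CPM (log2 fold change 6.88, SE 0.679), and Myb, a factor of early lymphoid progenitors, rose from 39.9 to 387 CPM (3.28, SE 0.0989). Cr2, the complement receptor of mature B cells (chromosome 1, 195136811 to 195176716), fell from 1306 to 53.2 CPM (-4.62, SE 0.195), and Fcer2a, encoding CD23, fell from 530 to 20.6 CPM (-4.69, SE 0.374). Phgdh rose from 72.8 ± 1.797 to 330 ± 14.2 CPM (2.18, SE 0.0497; adjusted p = 2.02e-11, edgeR quasi-likelihood test, Benjamini-Hochberg).

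All 52 S phase genes and all 52 G2 and mitosis genes rose, as did all adjusted over the list alone, with medians of 2.44 and 3.37. Examples were Hells (2.70), Pole, the leading strand polymerase (2.58), Cks1b (3.42) and Mad2l1, a checkpoint protein (2.12). Camera gave 5.21e-33 for S phase (adjusted p = 0.131 with an estimated correlation) and 1.51e-19 for G2 and mitosis (adjusted p = 0.24 with an estimated correlation). Of 68 MYC target genes 64 rose and 3 fell (64 and 3 adjusted over the list alone; median 1.17), among them Cdk4 (114 to 411 CPM), Ldha, which makes lactate (240 to 974 CPM), and Srm, of polyamine synthesis (2.07). All 86 ribosome biogenesis genes, all 61 oxidative phosphorylation genes and all 40 proteasome and chaperone genes rose, also adjusted over the list alone, with medians of 0.83, 0.92 and 1.01. Examples were Fbl, the rRNA methyltransferase (1.51), Cycs, cytochrome c (1.65), and Psmd7, of the proteasome lid (1.54). Of 31 nucleotide synthesis genes 30 rose and 1 fell (30 and 1 adjusted over the list alone; median 1.44), with Dut, which removes dUTP, at 2.70. For the MYC targets camera gave 6.11e-24 and for nucleotide synthesis 2.37e-19 (adjusted p = 0.0701 with an estimated correlation for each). Ribosome biogenesis gave 5.8e-20 and oxidative phosphorylation 1.1e-17 (adjusted p = 0.155 with an estimated correlation for each), and the proteasome list gave 5.8e-20 (adjusted p = 0.131 with an estimated correlation). Cytosolic ribosomal proteins moved less, with 68 of 79 higher (69 adjusted over the list alone), a median of 0.49 and a camera adjusted p of 1.74e-05 (adjusted p = 0.553 with an estimated correlation).

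Transcripts of B cell maturity went the other way. All 22 mature follicular genes fell, also adjusted over the list alone (median -2.31), among them Icosl (-3.89) and Bcl2, the survival factor (166 to 25.1 CPM, -2.72). Of 21 marginal zone genes 18 fell and 1 rose (18 and 1 adjusted over the list alone; median -1.96), with S1pr3, which positions marginal zone cells, going from 106 to 5.34 CPM. NF-kB targets gave 21 lower and 1 higher of 22 (21 and 1 adjusted over the list alone; median -1.96), with Traf1 at -3.73 and Nfkb2 going from 245 to 49.0 CPM. All 10 MHC class II genes fell, also adjusted over the list alone (median -2.12), and Cd74, the invariant chain, went from 11429 to 2648 CPM. Camera gave 7.17e-20 for follicular genes (adjusted p = 0.121 with an estimated correlation), 1.74e-12 for marginal zone genes and 9.46e-19 for NF-kB targets (adjusted p = 0.0599 with an estimated correlation for each), and 4.95e-12 for MHC class II (adjusted p = 0.131 with an estimated correlation). Of 20 pro-B and pre-B genes 17 rose and 2 fell (17 and 2 adjusted over the list alone; median 2.38), with Sox4, needed for pro-B survival, at 3.26 (camera adjusted p = 4.54e-06, adjusted p = 0.128 with an estimated correlation). Germinal centre genes gave 10 lower and 2 higher of 15 (10 and 2 adjusted over the list alone; median -2.08), with Bcl6, the master repressor of that stage, going from 94.0 to 7.90 CPM, while Ezh2, a histone methyltransferase, rose by 3.05 (camera adjusted p = 0.0282, adjusted p = 0.287 with an estimated correlation). In the MYC and MAX network Mxd3 rose from 3.55 to 33.1 CPM, Mxi1 by 1.66 and Mxd4 by 0.82, and Mycl fell by 3.48.

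Markers of cells outside the B lineage moved with this comparison too, most of them lower and the erythroid ones higher. Of 23 T cell markers 22 fell and 1 rose (22 and 1 adjusted over the list alone; median -2.80; camera adjusted p = 2.24e-06, adjusted p = 0.155 with an estimated correlation). Of 22 monocyte and macrophage markers 19 fell and 0 rose (19 and 0 adjusted over the list alone; median -1.13; camera adjusted p = 0.0016, adjusted p = 0.424 with an estimated correlation). NK cell markers gave 9 lower and 0 higher of 13 (median -2.41; camera adjusted p = 0.0117, adjusted p = 0.424 with an estimated correlation) and dendritic cell markers 14 lower and 1 higher of 16 (median -2.59; camera adjusted p = 9.78e-05, adjusted p = 0.287 with an estimated correlation). Of 20 erythroid markers 15 rose and 0 fell (median 2.30; 8 rose without WT replicate 1 or 3 and 9 without EuMyc replicate 1 or 3), and camera did not call that list (adjusted p = 0.139), except without WT replicate 2 (adjusted p = 0.0477). These 3 lists had the same numbers adjusted over the list alone. In all, 9225 of 12878 genes differed between EuMyc and WT (4730 higher, 4495 lower) at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 3982 by over 2-fold. All 3 EuMyc libraries came from males by Xist and Y-linked transcripts, against 1 of 3 in each of WT and Max KO and 1 of 3 in EuMyc Max KO.

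**Figure D2:**
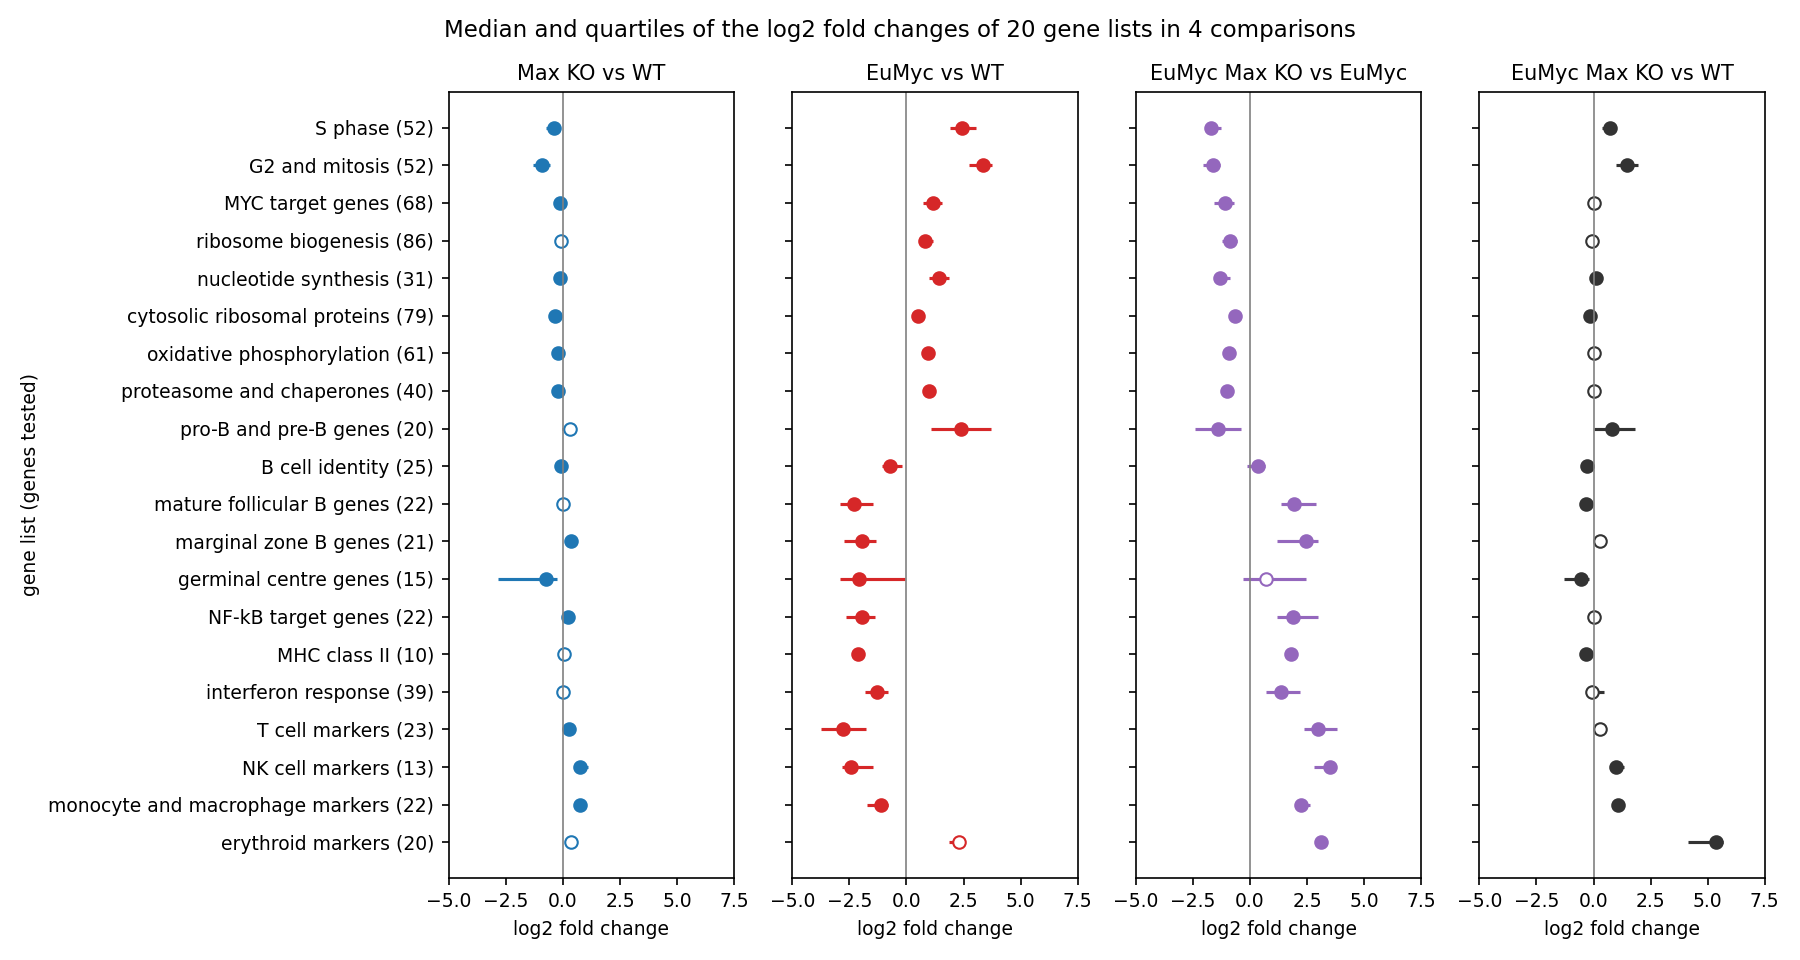
Median log2 fold change (points) and quartiles (lines) of 20 gene lists in 4 comparisons; filled points mark lists with a camera adjusted p under 0.05 at the preset correlation of 0.01, open points the rest. The S phase list had a median of 2.44 in EuMyc against WT, -1.69 in EuMyc Max KO against EuMyc and 0.70 in EuMyc Max KO against WT.

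EuMyc Max KO cells differed from EuMyc cells in the opposite direction for most of these genes. Phgdh fell from 330 ± 14.2 to 82.0 ± 1.66 CPM (log2 fold change -2.01, SE 0.0493; adjusted p = 5.07e-11, edgeR quasi-likelihood test, Benjamini-Hochberg), Cdk4 from 411 to 122 CPM, and Ldha from 974 to 308 CPM. Myb fell from 387 to 66.5 CPM (-2.54, SE 0.0951) and Sox4 by 2.37. In the other direction Cr2 rose from 53.2 to 1367 CPM (4.68), Bcl2 from 25.1 to 190 CPM (2.92, SE 0.101), Nfkb2 from 49.0 to 246 CPM (2.33) and Cd74 from 2648 to 9169 CPM (1.79). The largest decreases that did not rest on 1 library included Tmem132e (96.8 to 0.592 CPM, -7.34, SE 0.399), Uchl1, a ubiquitin hydrolase (54.5 to 0.988 CPM, -5.78, SE 0.274), and Ltbp4, which binds latent TGF-beta (105 to 2.001 CPM, -5.71, SE 0.189). Among the largest increases were Ccl22, a chemokine (0.227 to 11.3 CPM, 5.63), and Il9r (6.64 to 219 CPM, 5.05).

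Of 68 MYC target genes 60 fell and 2 rose (61 and 2 adjusted over the list alone; median -1.10), and of 86 ribosome biogenesis genes 84 fell and 0 rose, with the same numbers adjusted over the list alone (median -0.89). Nolc1, a nucleolar chaperone, fell by 1.70 and Dkc1, a pseudouridine synthase, by 1.85. Cytosolic ribosomal proteins gave 76 lower and 0 higher of 79 (77 and 0 adjusted over the list alone; median -0.64). All 61 oxidative phosphorylation genes and all 40 proteasome and chaperone genes fell, also adjusted over the list alone (medians -0.93 and -0.997). Camera gave 8.24e-23 for MYC targets (adjusted p = 0.134 with an estimated correlation) and for ribosome biogenesis (adjusted p = 0.146 with an estimated correlation), 3.66e-10 for ribosomal proteins (adjusted p = 0.402 with an estimated correlation), and 6.36e-19 and 1.48e-21 for oxidative phosphorylation and the proteasome list (adjusted p = 0.146 with an estimated correlation for each). All 52 S phase genes and 51 of 52 G2 and mitosis genes fell, as adjusted over the list alone, with medians of -1.69 and -1.62, among them Cdca7 (-3.02) and Cks1b (-2.37). Camera gave 1.48e-21 for S phase (adjusted p = 0.146 with an estimated correlation) and 1.78e-09 for G2 and mitosis (adjusted p = 0.361 with an estimated correlation).

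Mature follicular genes gave 20 higher and 0 lower of 22, marginal zone genes 19 and 0 of 21 and NF-kB targets 21 and 0 of 22, each with the same numbers adjusted over the list alone and with medians of 1.93, 2.46 and 1.89. Icosl rose by 3.70, S1pr3 by 4.02 and Traf1 by 3.75. Camera gave 3.75e-15 for the follicular list (adjusted p = 0.146 with an estimated correlation), and 8.17e-15 and 1.15e-19 for the other two (adjusted p = 0.0507 with an estimated correlation for each). Pro-B and pre-B genes gave 13 lower and 2 higher of 20, also adjusted over the list alone (median -1.38; camera adjusted p = 0.000344, adjusted p = 0.146 with an estimated correlation). Stag3 rose from 16.4 ± 2.54 to 124 ± 4.22 CPM (2.92, SE 0.177), and Smc1b, another meiotic cohesin subunit, by 3.52 and Ddx25, a helicase of male germ cells, by 2.69. With them, 6 of the 11 germline genes rose and 1, Brdt, fell, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.107). Mga and Mnt rose by 0.76 and 0.62, Mxd1 by 1.51 and Mycl by 3.16, and Mxd4 fell by 0.45. Mxd1 stood at 133, 89.4 and 34.9 CPM in EuMyc Max KO replicates 1, 2 and 3, against 27.3 to 33.3 in EuMyc, in the order of the erythroid transcripts of these libraries (9883, 6673 and 1820 CPM). Bmf fell by 1.33 and Trp53 by 0.92.

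T cell markers gave 22 higher and 0 lower of 23, also adjusted over the list alone (median 2.98; camera adjusted p = 1.8e-08, adjusted p = 0.146 with an estimated correlation), and all 22 monocyte and macrophage markers rose, also adjusted over the list alone (median 2.24; camera adjusted p = 1.41e-07, adjusted p = 0.277 with an estimated correlation), with Csf1r, the receptor of macrophage growth, going from 109 to 732 CPM. Of 20 erythroid markers 19 rose and 0 fell, also adjusted over the list alone (median 3.10; camera adjusted p = 0.0439, adjusted p = 0.651 with an estimated correlation). That call was lost without EuMyc replicate 2 or 3 or without EuMyc Max KO replicate 1 or 2, with an adjusted p of up to 0.0988. In all, 9494 of 12878 genes differed (4845 higher, 4649 lower) at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 4176 by over 2-fold.

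The extent of the reversal was counted gene by gene. Of the 4730 genes that were higher in EuMyc than in WT, 4082 were lower in EuMyc Max KO than in EuMyc, and of the 4495 that were lower, 3810 were higher. Together these were 7892 of 9225 genes, or 85.6%. Independent lists of these sizes would share 1708 and 1691 genes in those directions, but both comparisons use the EuMyc libraries and so are not independent. Only 126 and 15 genes moved further in their own direction. Among the 3982 genes changed by over 2-fold, the median share of the change left in EuMyc Max KO against WT was 0.105 (0 would be a full return, 1 no return). Across genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson r of -0.81 and a Spearman rho of -0.84. In 20 simulated data sets with unchanged groups, which share the EuMyc libraries in the same way, r was -0.49, the covariance was -0.0413 against -1.51 observed, 77.4% of all genes had opposite signs against 87.8% observed, and a mean of 0.05 genes per data set was called in opposite directions. With 3 EuMyc libraries the shared group could not be split into parts of at least 2, so the part due to sharing was not measured on the real libraries. In the simulation sharing alone gave much of r and of the share of opposite signs. It gave little of the covariance and almost none of the opposite calls. The covariance argues against noise that is independent from gene to gene in the shared libraries as the main source of the reversal. The opposite calls cannot bear on this, since groups without changes give few calls of any kind. A trait common to all 3 EuMyc libraries, such as their male sex, was not in the simulation.

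The effect of Max loss in normal and in EuMyc cells can be compared on separate libraries. Over all tested genes the log2 fold changes correlated at r = 0.48 (rho = 0.48, across genes). Of 936 genes higher in Max KO than in WT, 690 were also higher in EuMyc Max KO than in EuMyc, against 352 for independent lists, and of 997 lower genes 733 were also lower, against 360. Genes called in opposite directions numbered 113 and 117, against 338 and 375 for independent lists. Stag3, Il9r, Mnt and Mga rose and Cd79a, Bmf, Hells and Phgdh fell in both.

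**Figure D3:**
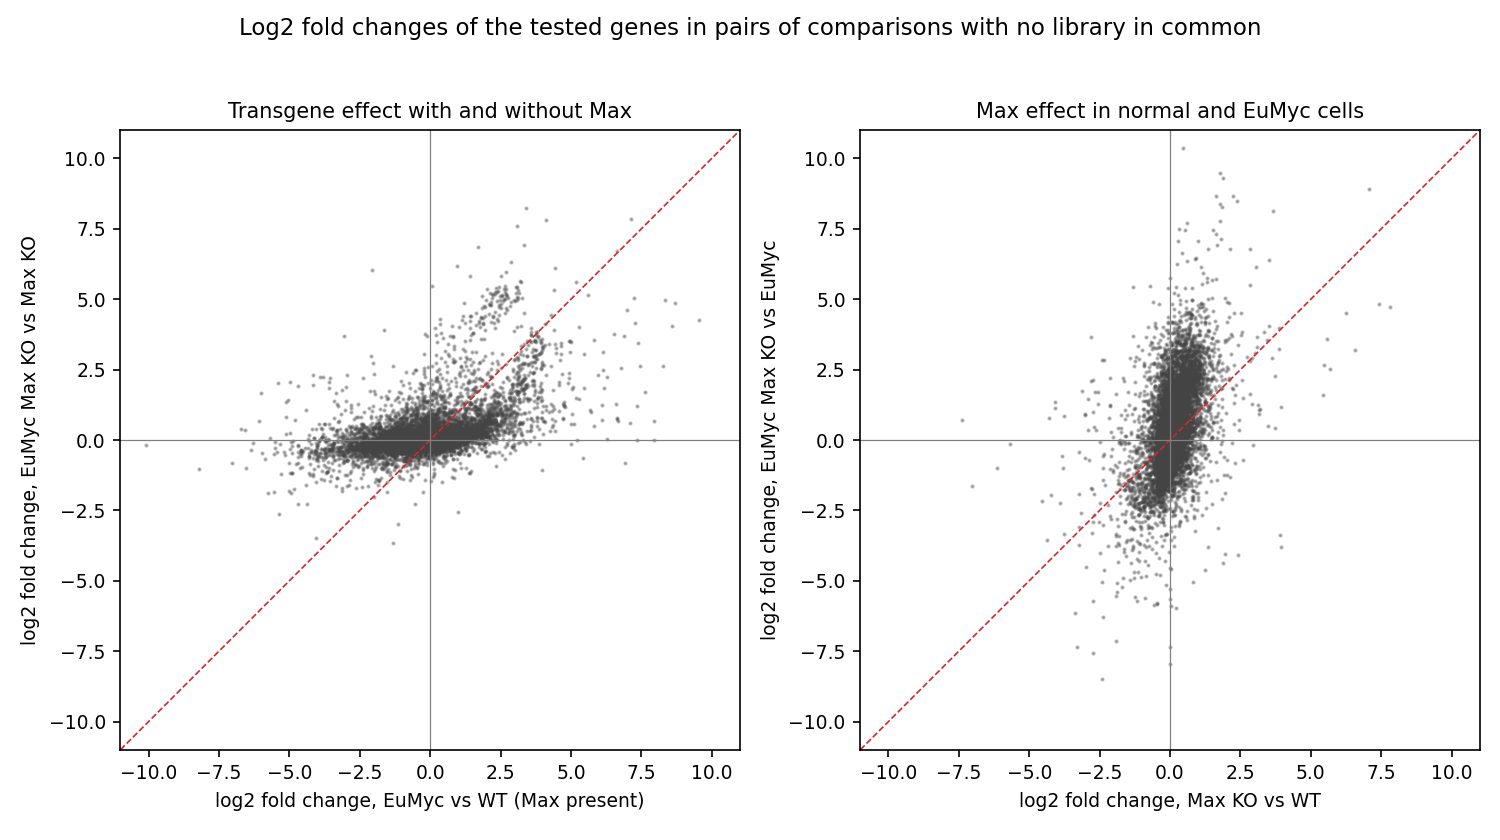
Log2 fold changes of all tested genes: on the left EuMyc against WT (x axis) and EuMyc Max KO against Max KO (y axis), on the right Max KO against WT (x axis) and EuMyc Max KO against EuMyc (y axis); each point is a gene and the dashed line marks equal values. Pearson's r across genes was 0.50 on the left and 0.48 on the right.

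The difference between these effects was tested as an interaction, in which a positive value means that Max loss raised a gene more, or lowered it less, in EuMyc than in normal cells. Phgdh, lowered by 0.51 in normal and by 2.01 in EuMyc cells, had an interaction below 0, as did Cdk4 (-1.47) and Myb (-2.65). Cr2 (4.12), Bcl6 (3.27) and S1pr2 (3.89) lay above 0, and S1pr2 fell in normal cells. All 86 ribosome biogenesis genes and 47 of 52 S phase genes had values below 0 that passed the test (86 and 49 adjusted over the list alone), and 21 of 22 mature follicular genes and 18 of 21 marginal zone genes had values above 0, with 1 marginal zone gene below (21 and 18 above adjusted over the list alone). Camera gave 6.15e-25 for ribosome biogenesis (adjusted p = 0.118 with an estimated correlation), 6.34e-17 for S phase (adjusted p = 0.194 with an estimated correlation) and 1.42e-20 for follicular genes (adjusted p = 0.087 with an estimated correlation). The marginal zone list, at 1.23e-15, was the only interaction call to hold with an estimated correlation (adjusted p = 0.0368 with an estimated correlation). For Stag3 the interaction was -0.70 with an adjusted p of 0.0291 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and leaving out any of 8 libraries (replicates 1 and 3 of WT, Max KO and EuMyc, or replicates 1 and 2 of EuMyc Max KO) ended the call, with an adjusted p of up to 0.0743. In total 7175 genes had an interaction (3586 above 0, 3589 below) at an adjusted p under 0.05 by the same edgeR test.

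The Myc transgene was also compared in cells without Max. EuMyc Max KO cells had more cell cycle and erythroid transcripts than Max KO cells. Camera called 23 of 42 lists, 18 higher and 5 lower, and 0 with an estimated correlation (8 at an unadjusted p under 0.05). Rrm2, the small subunit of ribonucleotide reductase, rose from 12.96 to 149 CPM (log2 fold change 3.52), Bub1b from 7.05 to 47.7 CPM (2.75), and Cks1b by 1.97. Car2, the carbonic anhydrase of red cells, rose from 30.8 to 645 CPM (4.39), and Ermap, an erythroid membrane protein, from 5.58 to 197 CPM (5.14). Phgdh rose from 51.3 ± 0.107 to 82.0 ± 1.66 CPM (0.68; adjusted p = 3.58e-05, edgeR quasi-likelihood test, Benjamini-Hochberg).

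Of 52 G2 and mitosis genes 51 rose and 0 fell (51 and 0 adjusted over the list alone; median 2.61; camera adjusted p = 1.01e-92, adjusted p = 0.139 with an estimated correlation). Of 52 S phase genes 47 rose and 0 fell (48 and 0 adjusted over the list alone; median 0.995; camera adjusted p = 2.32e-62, adjusted p = 0.139 with an estimated correlation). All but 1 of 20 erythroid markers rose (20 adjusted over the list alone; median 5.03; camera adjusted p = 2.4e-19, adjusted p = 0.232 with an estimated correlation). Summed over the erythroid markers the libraries held 360, 645 and 289 CPM in Max KO and 9883, 6673 and 1820 CPM in EuMyc Max KO, and the mean log2 CPM of the G2 and mitosis genes ranked the EuMyc Max KO libraries in the same order. MYC target genes gave 24 higher and 0 lower of 68 (28 and 0 adjusted over the list alone; median 0.16; camera adjusted p = 1.22e-05, adjusted p = 0.406 with an estimated correlation), with Srm at 0.55 and Pa2g4 at 0.46. Oxidative phosphorylation genes gave 30 higher and 0 lower of 61 (41 and 0 adjusted over the list alone; median 0.22; camera adjusted p = 8.34e-09, adjusted p = 0.406 with an estimated correlation). Mature follicular genes gave 5 lower and 0 higher of 22 (6 and 0 adjusted over the list alone; median -0.29; camera adjusted p = 1.39e-06, adjusted p = 0.406 with an estimated correlation). Germinal centre genes gave 6 higher and 0 lower of 15 (8 and 1 adjusted over the list alone; median 0.91; camera adjusted p = 4.79e-06, adjusted p = 0.148 with an estimated correlation), among them S1pr2 (1.74) and Mybl1 (1.87).

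**Figure D4:**
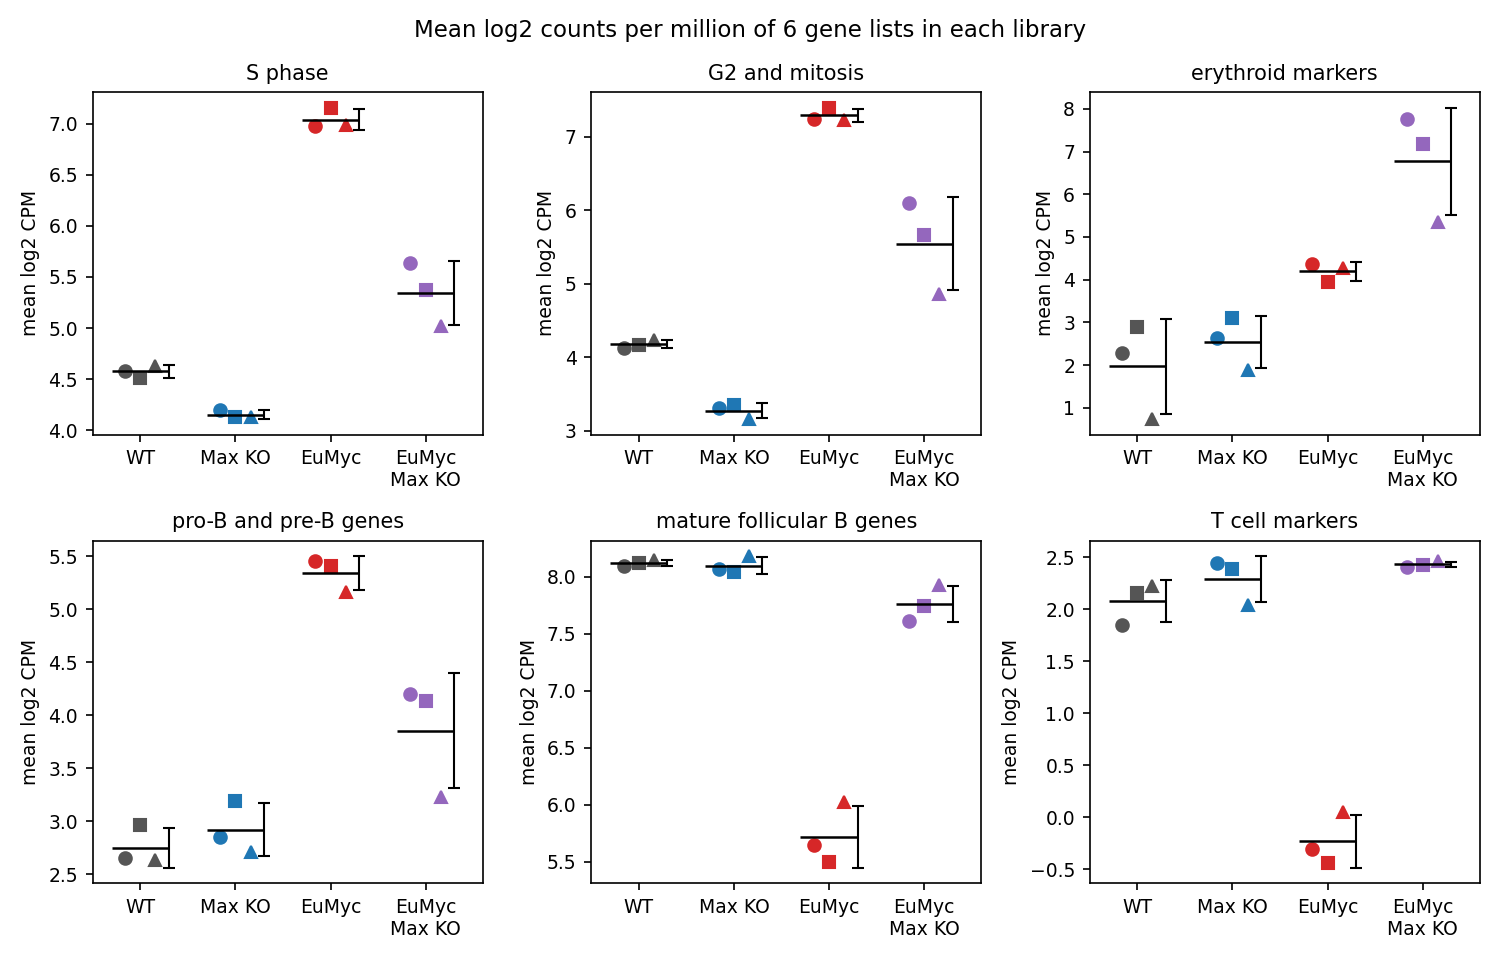
Mean log2 CPM over the tested genes of 6 lists in each library (circle, square and triangle for replicates 1, 2 and 3; lines are group means and bars SDs over n = 3; the vertical axes do not start at 0). Among the EuMyc Max KO libraries, which held 9883, 6673 and 1820 CPM of erythroid transcripts, the G2 and mitosis list ranks the replicates in the same order.

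In this comparison 1853 of 12878 genes passed the test (1378 higher, 475 lower; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05). The count was 1071 without Max KO replicate 1, 1078 without Max KO replicate 3, 1070 without EuMyc Max KO replicate 1, 1057 without EuMyc Max KO replicate 2 and 2846 without EuMyc Max KO replicate 3. It was 569 without the 2 erythroid-rich EuMyc Max KO libraries, an alternative chosen after the data were seen. With upper-quartile scaling the calls split into 1215 higher and 695 lower. Against 9225 genes for the transgene in cells with Max, the changes were smaller: across genes the log2 fold changes correlated at r = 0.50 (rho = 0.51) with a slope of 0.271. Of 4730 genes higher in EuMyc than WT, 1047 were also higher in EuMyc Max KO than Max KO (22.1%, 506 for independent lists). Of the 4495 lower genes, 407 were also lower (9.05%, 166 for independent lists). Opposite calls numbered 15 and 60, against 174 and 481. Of 20 erythroid markers 15 were higher in EuMyc than in WT and 19 in EuMyc Max KO than in Max KO. The overlap therefore cannot be credited to the transgene alone. Without the 2 erythroid-rich libraries r was 0.40.

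EuMyc Max KO cells were last compared with WT cells. The MYC and MAX network held 7 genes higher and 0 lower of 11 (7 and 1 adjusted over the list alone; median 0.49; camera adjusted p = 1.22e-05), which alone among the 17 lists called here held with an estimated correlation (adjusted p = 0.0468 with an estimated correlation). They were Myc itself (2.31), Mnt (0.49), Mga (0.50), Mxd1 (1.82), Mxd3 (2.18), Mxd4 (0.38) and Mxi1 (1.16). Myc is also the transgene of this group, so part of the list's shift follows from the design. The list was not tested without Myc. The estimated correlation between genes of this list was -0.0297, under the preset 0.01. In EuMyc Max KO replicates 1, 2 and 3, Mxd1 was at 133, 89.4 and 34.9 CPM, Mxd3 at 26.2, 16.6 and 5.51 CPM and Mxi1 at 71.4, 51.0 and 32.9 CPM, in the order of the erythroid transcripts (9883, 6673 and 1820 CPM). Without the 2 erythroid-rich libraries 4 of the 11 genes were higher and 0 lower (median 0.48). Of 52 G2 and mitosis genes 47 rose and 0 fell (52 and 0 adjusted over the list alone; median 1.46; camera adjusted p = 4.98e-27, adjusted p = 0.378 with an estimated correlation), and of 52 S phase genes 40 rose and 0 fell (43 and 0 adjusted over the list alone; median 0.70; camera adjusted p = 7.11e-19, adjusted p = 0.378 with an estimated correlation). All 20 erythroid markers rose, also adjusted over the list alone (median 5.38; camera adjusted p = 1.13e-16, adjusted p = 0.378 with an estimated correlation). The MYC target list was not called (16 higher and 5 lower of 68, 17 and 6 adjusted over the list alone; camera adjusted p = 0.154), and its median of 0.03 went as low as -0.0056 under other scalings between libraries. Ribosome biogenesis was not called either (7 higher and 7 lower of 86, 6 and 6 adjusted over the list alone; median -0.06; camera adjusted p = 0.281).

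Of 25 B cell identity genes 15 fell and 0 rose (18 lower and 1 higher adjusted over the list alone; median -0.29; camera adjusted p = 2.74e-09, adjusted p = 0.378 with an estimated correlation). Cd79a, at 676 ± 74.0 CPM, fell by 1.504 on the log2 scale, and Spib, a factor of B cell receptor signalling, by 0.52. Germinal centre genes gave 8 lower and 1 higher of 15 (10 and 1 adjusted over the list alone; median -0.54; camera adjusted p = 3.59e-05, adjusted p = 0.253 with an estimated correlation), with S1pr2 at -1.26. Stag3 was higher by 3.35 and Ccnd2 by 0.98. Monocyte and macrophage markers gave 18 higher and 0 lower of 22 (19 and 0 adjusted over the list alone; median 1.06; camera adjusted p = 1.38e-08, adjusted p = 0.398 with an estimated correlation), with Apoe at 1.31. In all, 3581 genes differed from WT (2190 higher, 1391 lower; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05). The count was 2379 without EuMyc Max KO replicate 1 and 932 without the 2 erythroid-rich libraries.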

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

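The tests of other label assignments were planned, and list medians under RLE and upper-quartile factors were added after the data were seen. Every result here stood out because the difference between libraries with and without Max was not the same in EuMyc as in normal mice. It was judged by the interaction term of the edgeR model or, for gene lists, by camera on that term. Each library holds a mix of cells. Pro-B and pre-B genes (median -1.38) and T cell markers (2.98) also differed between EuMyc Max KO and EuMyc. A change in the mix of cells therefore cannot be told apart from a change within cells. Of the 31 lists camera called, only marginal zone genes kept the call with an estimated correlation (adjusted p = 0.0368). The others had adjusted p values of 0.0596 (NF-kB targets) to 0.666 (cytosolic ribosomal proteins) with an estimated correlation. The interaction passed for 7175 of 12878 genes. When the Max labels were reassigned within normal and within EuMyc libraries, 10 of 100 drawn assignments, the real one included, called as many genes, and the highest other called 8691, so this count alone does not exclude chance. The draws point to the structure of the samples. All 10 were among the 15 draws that kept the real division of the EuMyc and EuMyc Max KO libraries, where at least 6754 genes were called, and the 85 draws that broke it called at most 2. The count therefore rests on the division within EuMyc mice, where 9494 genes differed between EuMyc Max KO and EuMyc. It says little about how the normal libraries divide.

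For growth and cell cycle lists the median interaction lay below 0. It was -0.98 for MYC target genes (median change -1.10 in EuMyc and -0.13 in normal cells), -0.82 for ribosome biogenesis (-0.89 and -0.08), -0.32 for cytosolic ribosomal proteins (-0.64 and -0.35), -0.78 for mitochondrial ribosomal proteins and -0.67 for translation factors. It was -1.10 for nucleotide synthesis, -1.19 for serine, one-carbon and polyamine metabolism, -0.50 for glycolysis, -0.71 for oxidative phosphorylation, -0.50 for amino acid handling (with a median of 0.0014 in normal cells, and between -0.0192 and 0.0419 there under other scalings), -0.80 for proteasome and chaperones and -0.60 for heat shock genes. The S phase list stood at -1.26 (-1.69 and -0.40) and the G2 and mitosis list at -0.81 (-1.62 and -0.92). Pro-B and pre-B genes gave -1.77, and subunits of the MGA repressor complex -0.38.

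For lists of mature B cells and of other cell types the median interaction lay above 0. It was 0.46 for B cell identity, 1.94 for mature follicular genes (1.93 in EuMyc and 0.02 in normal cells, where other scalings gave values as low as -0.0019, the mean was -0.03 and camera, pointing lower, made no call), 1.97 for marginal zone genes (2.46 and 0.37) and 2.0045 for B1 cell genes. Germinal centre genes gave 2.87, with a median of 0.72 in EuMyc and -0.74 in normal cells. They started low in EuMyc (median -2.08 against WT, 10 lower and 2 higher of 15), and their median in EuMyc Max KO was still below WT (-0.54). Plasma cell genes gave 0.92, activation genes 1.497, NF-kB targets 1.64, MHC class II 1.73, interferon response genes 1.495 and lysosome genes 0.59. Among markers of other cell types the values were 2.61 for T cells, 2.39 for NK cells, 1.42 for monocytes and macrophages and 2.28 for dendritic cells.

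Of single genes, Enpep (-6.26), Rbm24 (-6.16, and between -6.92 and -4.87 without Max KO replicate 2 or EuMyc Max KO replicate 1), Uchl1 (-5.30), Hspa12b (-5.30) and Ltbp4 (-4.54) had the lowest values. In the MYC and MAX network the values were -1.21 for Myc, -0.76 for Mxd4, 1.75 for Mxd1 and 2.68 for Mycl, and without EuMyc replicate 2 the Mxd1 call was lost at an adjusted p of 0.0511 by the edgeR test. Among the highest values were those of Prg2 (6.75, and up to 7.88 without Max KO replicate 2), Gcsam (6.46), Fras1 (5.47), Rgcc (5.23, and between 4.61 and 5.98 without Max KO replicate 1 or EuMyc Max KO replicate 1) and Abcb1a (5.21).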

How the results depend on the processing

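Chosen after the data were seen were the sex term and the fit without the 2 erythroid-rich EuMyc Max KO libraries, which leaves 1 library assumed to vary like the other groups. In order (Max KO vs WT, EuMyc vs WT, EuMyc Max KO vs EuMyc, EuMyc Max KO vs Max KO, EuMyc Max KO vs WT, interaction), a test against 1.5-fold called 90, 4877, 5110, 480, 631 and 3119 genes, by its stricter threshold. Fitted on the compared libraries only, EuMyc Max KO vs Max KO gave 851 genes. Without the erythroid-rich libraries it gave 569, and EuMyc Max KO vs WT gave 932, from fewer samples. Leaving out 1 library gave 808 to 1565 genes for Max KO vs WT, 1057 to 2846 for EuMyc Max KO vs Max KO and 2379 to 4236 for EuMyc Max KO vs WT (values by library stand beside the counts), and counts within 1.5 times for the other contrasts. The replicate numbers showed no pairing of the mice across all groups. Same-numbered deviations from the group means correlated at -0.117 to 0.344, and the own number correlated best in 13 of 36 comparisons. Between WT and Max KO they correlated at 0.179, 0.344 and 0.0951 for numbers 1, 2 and 3. The sexes read from Xist and Y-linked transcripts also matched by number there, so pairing of these groups is not excluded. With a replicate block the fits called 1738, 9181, 9440, 1822, 3430 and 7116 genes. RLE factors, upper-quartile factors, library totals, both filters, DESeq2, limma-voom, the sex term and haemoglobin left out gave counts within 1.5 times. The median of all genes in EuMyc vs WT, EuMyc Max KO vs EuMyc and the interaction was 0.0119, 0.028 and 0.0239 with TMM, -0.1152, 0.1159 and 0.1133 with upper-quartile factors and -0.0922, 0.1481 and 0.1047 with library totals. At these depths 52.2% to 67.2% of simulated 1.5-fold changes were recovered in contrasts of a pair of groups and 38.8% in the interaction; depth itself was not varied.

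With an estimated correlation camera called 1, 0, 0, 0, 1 and 1 of 42 lists (4, 13, 12, 8, 5 and 16 at an unadjusted p under 0.05). A correlation above the preset is not the whole reason. In EuMyc vs WT the amino acid list had an estimated correlation of 0.0046, under the preset 0.01. Its camera adjusted p still went from 0.00139 to 0.0701. The cause was not tested further. The fry test in a single direction called 13, 40, 40, 27, 22 and 36 lists in the same order of contrasts. In either direction it called 39, 42, 42, 38, 39 and 40. Unlike camera, fry does not compare a list with other genes. The correlation of Max effects was 0.39 without the erythroid-rich libraries and 0.41 to 0.47 with 1 library left out, lowest without Max KO replicate 2. That of Myc effects was 0.54 with a sex term and 0.40 without the erythroid-rich libraries, and the share of EuMyc vs WT calls moved back was then 78.3%. Xist, higher in EuMyc Max KO than in the all-male EuMyc group, stood at -0.15 with the sex term, which takes up that difference. Monocyte and macrophage markers in EuMyc Max KO vs Max KO, not called in the main result, turned lower without the erythroid-rich libraries (camera adjusted p = 0.00802); the cause was not tested. For each contrast of a pair of groups 10 splits of 3 against 3 exist, so no share under 0.1 can be had; the real split was the 1 split of 10 with as many genes, with 2458, 9302, 9027, 851 and 2629 genes by edgeR on the compared libraries against at most 1, 0, 0, 6 and 0 in another split.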

Other observations

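Tests chosen after the result was seen were the fit with an erythroid term, the sex term, the comparisons of Cd79a, list medians under RLE and upper-quartile factors and all values without the erythroid-rich libraries. Of 39 interferon response genes 32 fell in EuMyc against WT and 2 rose (32 and 2 adjusted over the list alone; median -1.28; camera adjusted p = 1.74e-05, adjusted p = 0.387 with an estimated correlation), and in EuMyc Max KO against EuMyc 34 rose and 0 fell (35 and 0 adjusted over the list alone; median 1.34; camera adjusted p = 7.09e-06, adjusted p = 0.356 with an estimated correlation). Tap1, the peptide transporter of MHC class I loading, stood at -1.32 and 1.34 in the same order, and Gbp2, a GTPase induced by interferon, at -1.77 and 1.71. Bbc3, which encodes PUMA and promotes cell death, was higher in EuMyc than in WT by 2.19 log2 units and in EuMyc Max KO than in WT by 1.55. Elovl6, a fatty acid elongase, rose by 3.58 in EuMyc against WT and fell by 3.05 in EuMyc Max KO against EuMyc. Cdkn1c, an inhibitor of cyclin-dependent kinases, fell by 4.89 in EuMyc Max KO against EuMyc.

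The EuMyc Max KO libraries differed among themselves. Replicates 1 and 2 held 9883 and 6673 CPM of erythroid transcripts against 1820 in replicate 3. Alas2, of haem synthesis, was at 1405, 992 and 325 CPM in replicates 1, 2 and 3. Transcripts of pancreatic enzymes, chosen after their values were seen, were present at low levels: Ctrb1 was at 6.06, 8.17 and 0.52 CPM and Pnlip at 5.30, 10.03 and 0.624 CPM in the same order, with at most 2.23 CPM of either in any WT or Max KO library and 0.053 CPM or less in EuMyc. By Xist and Y-linked transcripts replicates 1 and 2 were female and replicate 3 male. Reads mapping to more than 1 place ranged from 22.7% to 27.9% in this group.

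Of 52 G2 and mitosis genes 51 and of 52 S phase genes 47 were higher in EuMyc Max KO than in Max KO (adjusted p = 0.139 for each list with an estimated correlation), and RNA from erythroid cells, which B220 selection would remove, is a candidate explanation. Beside the summed CPM of 20 erythroid markers (17 of them at 1 CPM or more in WT, 0 shared with another list), the median group term of 52 G2 and mitosis genes was 1.52 times the Max KO mean (quartiles 0.425 and 2.03) against 5.11 without the erythroid term. That of 52 S phase genes was 0.4525 (quartiles 0.2058 and 0.9905) against 0.9948, so much of the difference moved with erythroid transcripts. Some markers of other cells moved alike. In EuMyc Max KO replicates 1, 2 and 3 Rag1 was at 16.1, 11.9 and 2.29 CPM and S100a9, of neutrophils, at 76.3, 70.7 and 6.91 CPM. Cd3e, of T cells, did not follow that order (3.84, 5.10 and 4.37 CPM). The erythroid term therefore cannot tell erythroid cells from other cells that vary with them. Without EuMyc Max KO replicate 3 the medians were 0.232 (quartiles -0.614 and 1.68) and 0.1776 (quartiles -0.0686 and 0.5434), so the remainder rests on that library and the share of erythroid RNA cannot be told apart from an effect of the transgene. In that library alone 45 of 52 G2 and mitosis genes were higher (median 1.81) and 39 of 52 S phase genes (median 0.68). By Xist and Y-linked transcripts only replicate 2 of Max KO and only replicate 3 of EuMyc Max KO were male. This balance argues against the sex of the mice as the cause. Because of it a sex term could hardly move the G2 and mitosis median, which was 2.57 with the term and 2.61 without. The SE of 0.179 with the term is over genes and does not measure the spread between mice. Cells that kept Max stay open as untested.

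Cd79a was lower in both groups without Max, at -1.22 log2 units in Max KO against WT and -0.43 in EuMyc Max KO against EuMyc. A candidate explanation is a Cre allele inserted in Cd79a, as in the mb1-Cre mouse, which the labels do not name. The log2 ratio of Cd79a to Cd79b changed by -0.85 (SE 0.0702) in Max KO against WT and by -0.78 (SE 0.0533) in EuMyc Max KO against EuMyc. Each fall was short, by more than its SE, of the 1 log2 unit that loss of a single functional copy would give. The ratio also rests on Cd79b. Its CPM was 2149, 1921 and 1841 in WT and 1464, 1490 and 1653 in Max KO. It was 1010, 946 and 1190 in EuMyc and 1220, 1281 and 1503 in EuMyc Max KO. A lower share of B cells as the whole cause was argued against, since the other 24 B cell identity genes had a median of -0.0691 (quartiles -0.13 and 0.05). Direct regulation of Cd79a by MAX complexes was not tested.

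In Max KO against WT 58 of 79 ribosomal protein, 24 of 61 oxidative phosphorylation and 16 of 40 proteasome and chaperone genes were lower by small amounts, and the list calls were lost at adjusted p = 0.541 with an estimated correlation. After removal of the trend with transcript length and GC content, which took up 0.763% of the variance, the ribosomal proteins had a median of -0.33 (quartiles -0.40 and -0.26) against -0.35 before, and oxidative phosphorylation and the proteasome list -0.20 and -0.19. Over 3 other scalings the highest medians were -0.31 (quartiles -0.38 and -0.25), -0.17 (-0.23 and -0.12) and -0.16 (-0.20 and -0.11), each with library totals, and with each library left out in turn the highest were -0.30, -0.17 and -0.15, each without WT replicate 1. These values argue against length and GC content, the choice among these scalings and a single library as the whole cause. Reads shared with pseudogenes, lower growth of cells without MYC and MAX dimers and a shift in the mix of B cell stages stay open as untested.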
